A study of Mus musculus with 3 samples.

How the data were processed

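Per the labels, total RNA of mouse regulatory T cells (strain C57BL/6NJ, primary cells) was sequenced in 3 libraries, numbered biological replicates 2, 3 and 4. They form 1 group, and no second condition was analysed here. All 3 carry the same donor identifier, the sex field reads "not collected" and the age is unknown, so the labels do not say whether the libraries came from separate animals; levels of Xist and Y-linked genes, which bear on this, are in the results. The SDs below measure only the spread between these libraries, part of which may be technical. With 3 libraries a sign-flip p-value is 0.25 whenever all differences share a sign, whatever their spread. The p-values of the list tests rest on the spread among genes, and those of the chi-square test on counting error. The assay label names total RNA sequencing, whereas the name of the linked library protocol refers to polyadenylated RNA; the linked differentiation protocol, by its name, is for CD4 T cells. Per the file headers, the samples had been activated for 16 hours, a detail the labels leave out.

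The authors deposited raw fragment counts per gene, with the merged exon length and coordinates of each gene. Per the file headers, the counts were made with featureCounts 1.4.6-p4 on paired-end, reverse-stranded alignments (strand option 2), over exons of the GENCODE mouse M13 annotation, keeping pairs with both ends aligned. The genome build is mm10 per the labels. The alignment file names in the headers refer to STAR; its exact version, its settings and any trimming are not given in the sources used here. The command in the headers has no option for counting fragments that align to several places or overlap several genes. By that program's defaults such fragments are left out, so near-identical genes (histones, hemoglobins, the H2-Q genes, the mitochondrial genes that overlap a neighbour) can be undercounted and are reported as uncertain. Strand was used in the counting, so antisense genes are told apart.

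The design had been written for deposited TPM (transcript abundance scaled for gene length and library total). The deposited files hold counts instead, so TPM was computed here as count over exon length, scaled to the same TPM total in each library. All 50600 gene identifiers were kept. Symbols and biotypes came from GENCODE mouse release M21 by unversioned identifier: 50376 matched, and the 224 without a symbol held 0.00804% to 0.0104% of fragments (95% Wilson intervals within 0.00778% and 0.0108%). Coordinates are those of the deposited files, 1-based. Totals were 41222058, 47665060 and 99097524 fragments in replicates 2, 3 and 4, so that 3 fragments were worth 0.0728, 0.0629 and 0.0303 CPM (counts scaled for library total only). A gene without a fragment is given with the TPM that 3 fragments would make in the shallowest case. Intervals and such floors cover counting error only, because no molecular identifiers were used.

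Before the data were examined, 42 gene lists, the tests, the processing alternatives and the rule for naming genes were fixed. Detection meant at least 1 TPM in every library. Foxp3 was set against Tbx21, Gata3 and Bcl6 within each library as log2((TPM + 1)/(TPM + 1)), with an exact two-sided sign-flip permutation test over 3 libraries, whose smallest possible p is 0.25. The level of a list was the median over its members of the mean log2(TPM + 1). It was placed among 10000 random lists of the same size from the 21764 protein-coding genes, with a two-sided p adjusted over the 42 lists (Benjamini-Hochberg); the smallest adjusted p this gave is 0.00084. The Treg core list was set against 5 lists of other CD4 T cell states by permuting genes between the lists (100000 resamples, two-sided). Genes are not independent replicates, so the list tests describe these libraries.

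With 1 group, the quasi-likelihood test of edgeR has nothing to compare. Libraries were compared by a chi-square test of equal rates for each gene (2 degrees of freedom, summed count of 30 or more) on effective library sizes from trimmed means of M values (TMM, edgeR 4.0.16 in R 4.3.3). A gene was called at an adjusted p under 0.05 and a highest-to-lowest CPM ratio of 2 or more, with a lowest value of 0 replaced by 3 fragments. That test takes fragments as independent and compares these libraries, not conditions. The common biological coefficient of variation came from edgeR with an intercept only. For list differences, the median over members of log2(CPM + 0.5), library minus the mean of the other 2, was placed among 10000 random lists matched on mean expression in 20 bins; lists with 5 or more tested members entered, and values outside the 2.5 to 97.5 percentiles were noted. Remaining steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

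The steps were tested on simulated data. For the comparison of libraries, over 13689 genes, 92 of 100 genes changed 2.5-fold and 94 of 100 changed 4-fold were called, with 1 of 13494 unchanged genes. For list differences, lists of 15 were drawn only from those of the same genes at 5 CPM or more. Of these, 4 of 100 random lists lay outside and 100 of 100 lists raised by 0.3 (log2) did. The real lists also held tested members below that level, such as Fos and Fosb, for which these rates may not hold. The counts simulated for both steps held counting noise only, whereas the real libraries varied beyond it. The 1 of 13494 is therefore not the false call rate of the real comparison. For list levels over 21764 genes, 3 of 100 random lists had an unadjusted p under 0.05, against 32 of 100 lists raised by 3 (log2), so that most clearly raised lists of that size were missed and a list not set apart may still be raised. For the core list comparison over the same genes, 7 of 100 unchanged pairs and 99 of 100 pairs set apart by 6 (log2) passed.

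Named genes followed a fixed rule: all members of the Treg core list; of every other list the 2 highest and 2 lowest by mean TPM; a fixed set of lineage factors and cytokines; the 10 protein-coding genes of highest mean TPM outside the mitochondrial genome; the 20 protein-coding genes with the largest ratio between libraries among called genes with a mean count of 100 or more; and Xist with the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. Some genes covered by the design and this rule are not reported here. Genes named outside it are said to be chosen after their values were seen. Alternatives covered the pseudocount, the CPM offset, log2(TPM + 1) for list differences, FPKM (counts scaled for gene length and library total) computed from the counts, the TPM denominator, DESeq2 1.42.0 size factors, unscaled totals, count and ratio minimums, counts divided by 2, and leaving out each replicate. Centring on GC content (of each gene's longest M21 transcript) or exon length and leaving out chromosomes X and Y were added after the data were seen.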

Results

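Regulatory T cells (Treg), the CD4 T cells that depend on the transcription factor Foxp3 and restrain immune responses, were profiled by RNA sequencing in 3 libraries of primary mouse cells. With 1 group, the design allows comparisons between genes within each library and between the 3 libraries. Replicates 2, 3 and 4 held 41222058, 47665060 and 99097524 assigned fragments. Of 50600 annotated genes, 11273 reached 1 TPM in every library, among them 9926 of 21764 protein-coding genes. Protein-coding genes took 98.8%, 99.0% and 98.9% of fragments (95% Wilson intervals 98.77% to 98.78%, 98.99% to 99.0005% and 98.89% to 98.90%). Across 13688 genes, log2 CPM values correlated between libraries with Pearson's r of 0.994 to 0.996 (genes are not independent replicates). The median coefficient of variation of TPM was 6.09% over 7568 protein-coding genes at 10 TPM or more, and the common biological coefficient of variation was 11.1%. The chi-square statistic per gene between any pair was 16.7 to 24.8, above the value of 1 that sampling alone gives, so no pair agreed within sampling noise and all 3 were counted.

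Genes of the Treg core list were abundant as a group, in samples that had been activated for 16 hours per the file headers. Il2ra and Tnfrsf9 are also in the T cell activation list, and Il2ra, Il2rb and Socs2 in the interleukin-2 and STAT5 list. The levels of these shared genes therefore do not tell Treg identity from activation. Foxp3 itself (ENSMUSG00000039521.12, chromosome X, 7579676 to 7595243, mm10) stood at 80.9 ± 3.97 TPM (SD, n = 3). The costimulatory receptor gene Tnfrsf4 (OX40) was highest of the 22 core members at 1524 ± 70.1 TPM. The interleukin-2 receptor chains Il2rb and Il2ra followed at 883 ± 32.4 and 658 ± 23.3 TPM, with the chemokine receptor Ccr8 at 873 ± 39.3, the actin-capping gene Capg at 449 ± 30.3, Tnfrsf18 (GITR) at 405 ± 23.2 and the inhibitory receptor Ctla4 at 351 ± 37.5. Tnfrsf9 (4-1BB) reached 182 ± 9.04 TPM, Icos 92.2 ± 9.22, the folate receptor family gene Izumo1r 78.1 ± 3.83, Cd83 60.4 ± 3.02, the Ikaros family factor Ikzf4 (Eos) 56.1 ± 6.14, Lrrc32 (GARP) 43.9 ± 2.01 and Nt5e (CD73) 37.1 ± 3.36.

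Other core members were scarce. Gpr83, Tigit, Nrp1 and Socs2 lay between 10.8 and 18.3 TPM on average. Ikzf2 (Helios; chromosome 1, 69531214 to 69687245), a factor often used together with Nrp1 to mark thymus-derived Treg cells, was at 3.22 ± 0.655 TPM. The integrin gene Itgae (CD103) was at 0.646 ± 0.354 TPM and the ectonucleotidase gene Entpd1 (CD39; chromosome 19, 40612366 to 40741602) at 0.157 ± 0.119, from 7, 6 and 48 fragments. In all, 20 of 22 core members reached 1 TPM in every library, 18 reached 10 and 8 reached 100. The list median was 69.2 TPM, above all 10000 random lists (adjusted p of the random-list permutation = 0.00084, from the smallest p they can give).

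**Figure D1:**
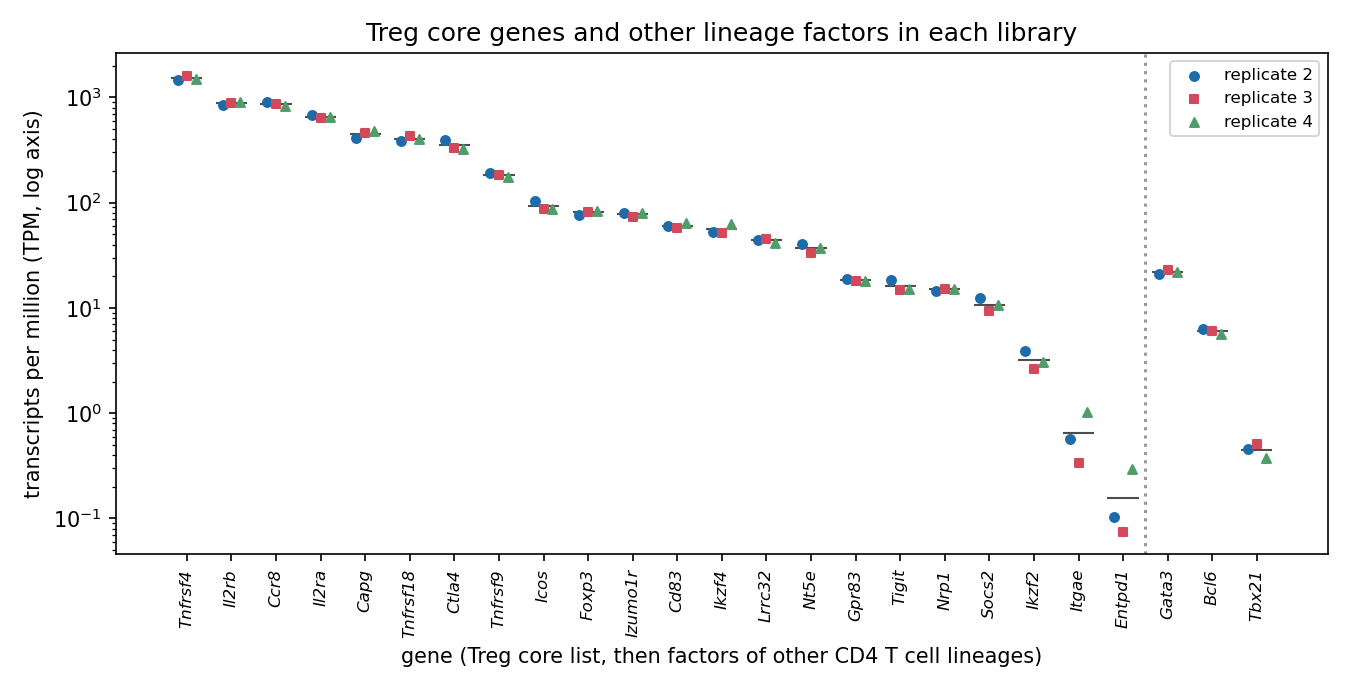
Level in TPM (log axis) of the 22 Treg core genes and 3 factors of other CD4 T cell lineages in replicates 2, 3 and 4; short horizontal lines mark the mean of the 3 libraries. Foxp3 averaged 80.9 TPM and Gata3 21.8, while Entpd1 and Tbx21 averaged under 1 TPM.

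Among the factors that define CD4 T cell lineages, Foxp3 exceeded Tbx21 (T-bet, Th1), Bcl6 (follicular helper, Tfh) and Gata3 (Th2) in 3 of 3 libraries. Tbx21 was at 0.446 ± 0.068 TPM, Bcl6 at 5.996 ± 0.291 and Gata3 at 21.8 ± 0.91 (SD, n = 3). The mean log2 difference from Foxp3 was 5.82 ± 0.12 for Tbx21, 3.55 ± 0.13 for Bcl6 and 1.84 ± 0.05 for Gata3. In single libraries the differences ran from 5.73 to 5.95 for Tbx21, 3.41 to 3.66 for Bcl6 and 1.81 to 1.89 for Gata3. Each of the 3 exact two-sided sign-flip permutation tests gave p = 0.25, the smallest that 3 libraries allow, so none can pass a threshold of 0.05.

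Ifng, Il4, Il17a and Il21, cytokines of other helper lineages, were close to absent, as was Il10 of the Treg effector list. Ifng had 1 fragment in all and Il10 had 2, where 3 fragments would make 0.19 and 0.188 TPM. Il4 had 3 fragments and Il17a 4, all below 0.21 TPM in every library, and Il21 was at most 0.0623 TPM. Il2, which is silenced in most Treg cells, was at 159 ± 15.6 TPM (142, 173 and 161 TPM in replicates 2, 3 and 4; chromosome 3, 37120523 to 37125959).

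The core list stood above the lineage lists of other helper cells except that of Tfh. Its median log2(TPM + 1) exceeded that of the Th17 list by 5.93 (5.87 to 5.89 within single libraries, SD 0.01, adjusted permutation p = 0.0008), the Th2 list by 5.77 (0.28, p = 0.0016) and the Th1 list by 4.66 (0.15, p = 0.0019). The difference from the Tfh list was 2.12 (0.13, adjusted permutation p = 0.127), and that from the conventional T list was -0.81 (0.06, p = 0.455), neither past the threshold. All 5 differences kept their sign in the 3 libraries. The 3 differences past the threshold rested on members without expression: among members at 1 TPM or more in a library they were 1.18 for Th17 (5 members left), 1.00 for Th2 (4 members) and 2.45 for Th1 (10 members), with adjusted permutation p of 0.531, 0.531 and 0.363.

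Single members of the lineage lists were high. In the Th1 list, the cytokine Tnf reached 552 ± 23.8 TPM and the chemokine Ccl4 153 ± 22.6, while Hlx had no fragment (3 fragments would make 0.108 TPM). Il4ra (99.7 ± 9.27 TPM) and Ccr4 (67.4 ± 3.57) led the Th2 list, in which Ccr3 and Ptgdr2 had no fragment. In the Th17 list the chemokine receptor Ccr6 was at 34.2 ± 4.01 TPM, with no fragment of Il22 or Il23r in any library (at most 0.221 and 0.0988 TPM for 3 fragments). Pdcd1 (PD-1, 400.1 ± 25.3 TPM) and Cd200 (252 ± 15.6) led the Tfh list, and Ascl2 was at 0.101 ± 0.134. Median TPM was 1.76, 0.315, 0.146 and 15.02 for the Th1, Th2, Th17 and Tfh lists, at percentiles 66.5, 40.6, 41.3 and 90.5 of random lists, none set apart (adjusted p = 0.422 for Tfh and 0.905 for the rest).

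Genes of naive and conventional T cells were expressed beside the Treg genes. The T cell factor Tcf7 (TCF-1) was at 1017 ± 26.2 TPM and the lymph node homing receptor Ccr7 at 1263 ± 45.1, with Igfbp4 at 381 ± 29.9. Il7r, which also marks naive T cells, was low at 5.25 ± 1.07 TPM. All 10 conventional T genes and all 9 naive or recirculating T genes reached 1 TPM in every library, and the medians of 126 and 71.5 TPM were above random lists (adjusted p = 0.00084 and 0.0198). Random lists drawn only from genes at 1 TPM or more in a library placed the naive list at percentile 93.8, no longer set apart.

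Activation genes were high and effector genes were split. Irf4, induced by T cell receptor signalling, was at 1572 ± 15.7 TPM and Myc at 825 ± 16.4, against Egr1 at 19.0 ± 2.01 and Nr4a2 at 4.39 ± 0.0858. All 14 activation genes reached 1 TPM in every library, with a median of 203 TPM (adjusted p = 0.00084). Of the 17 Treg effector genes, 7 reached 1 TPM in every library, led by Irf4 and Pdcd1, and 10 stayed below it in every library. Klrg1 had no fragment (3 fragments would make 0.174 TPM) and Areg, a tissue repair factor, had 1. The effector median was 0.162 TPM, at percentile 41.4 (adjusted p = 0.905).

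The cells carried the general T cell programme. Trac, the T cell receptor alpha constant gene, was at 1743 ± 26.3 TPM and Cd5 at 1030 ± 84.8, and the lowest of the 16 pan T cell genes, Cd3g and Cd247, were at 99.6 ± 11.5 and 110 ± 1.16 TPM. The median of that list was 457 TPM (adjusted p = 0.00084).

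Markers of other cell types were low, with exceptions by gene. The 9 neutrophil genes had no fragment in any library (3 fragments would make 0.324 TPM for Camp and 0.0806 for Cxcr2). In the mast cell or basophil list 5 of 6 genes had none, and Kit was at 1.67 ± 0.434 TPM. Erythroid genes were led by Klf1 at 0.466 ± 0.377 TPM, and 5 of 7 had no fragment, among them Hba-a1, whose near-identical copy makes it uncertain. Itga2b (1.06 ± 0.276 TPM) was the only platelet gene with a fragment among 5. Of 14 monocyte or macrophage genes, 13 stayed below 1 TPM, with Cd68 at 4.15 ± 1.16 and no fragment of C1qa or C1qb. Stroma, endothelium or epithelium genes were led by Pecam1 (4.2 ± 0.45 TPM) and Epcam (1.86 ± 0.282), and 9 of 11 stayed below 1 TPM.

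Lymphoid markers showed single high genes. Ighm, the IgM heavy chain constant gene (chromosome 12, 113418558 to 113422730), was at 282 ± 8.04 TPM, whereas Igkc was at 3.79 ± 2.18 and 8 of 12 B cell genes stayed below 1 TPM. Plasma cell genes were led by Sdc1 at 2.47 ± 0.31 TPM. Nkg7 (126 ± 8.83 TPM) and Cd8b1 (26.9 ± 2.6) stood out in the CD8 or cytotoxic list, with no fragment of Gzmk or Klrk1. The highest of 8 NK or ILC genes, Fcer1g, was at 0.744 ± 0.981 TPM, from 20, 3 and 3 fragments. Trdc (2.99 ± 0.299 TPM) led the gamma delta T list. Among dendritic cell genes, Cd74, the class II invariant chain, was at 35.7 ± 1.72 TPM and H2-Eb1 at 3.95 ± 1.70. Medians of the 12 lists of other cell types ran from 0 to 0.68 TPM at percentiles 5.78 to 49.9, and none was below random lists (lowest adjusted p = 0.463), since random protein-coding genes are often silent too. Against genes at 1 TPM or more in a library, 22 of the 42 lists were below random lists.

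**Figure D2:**
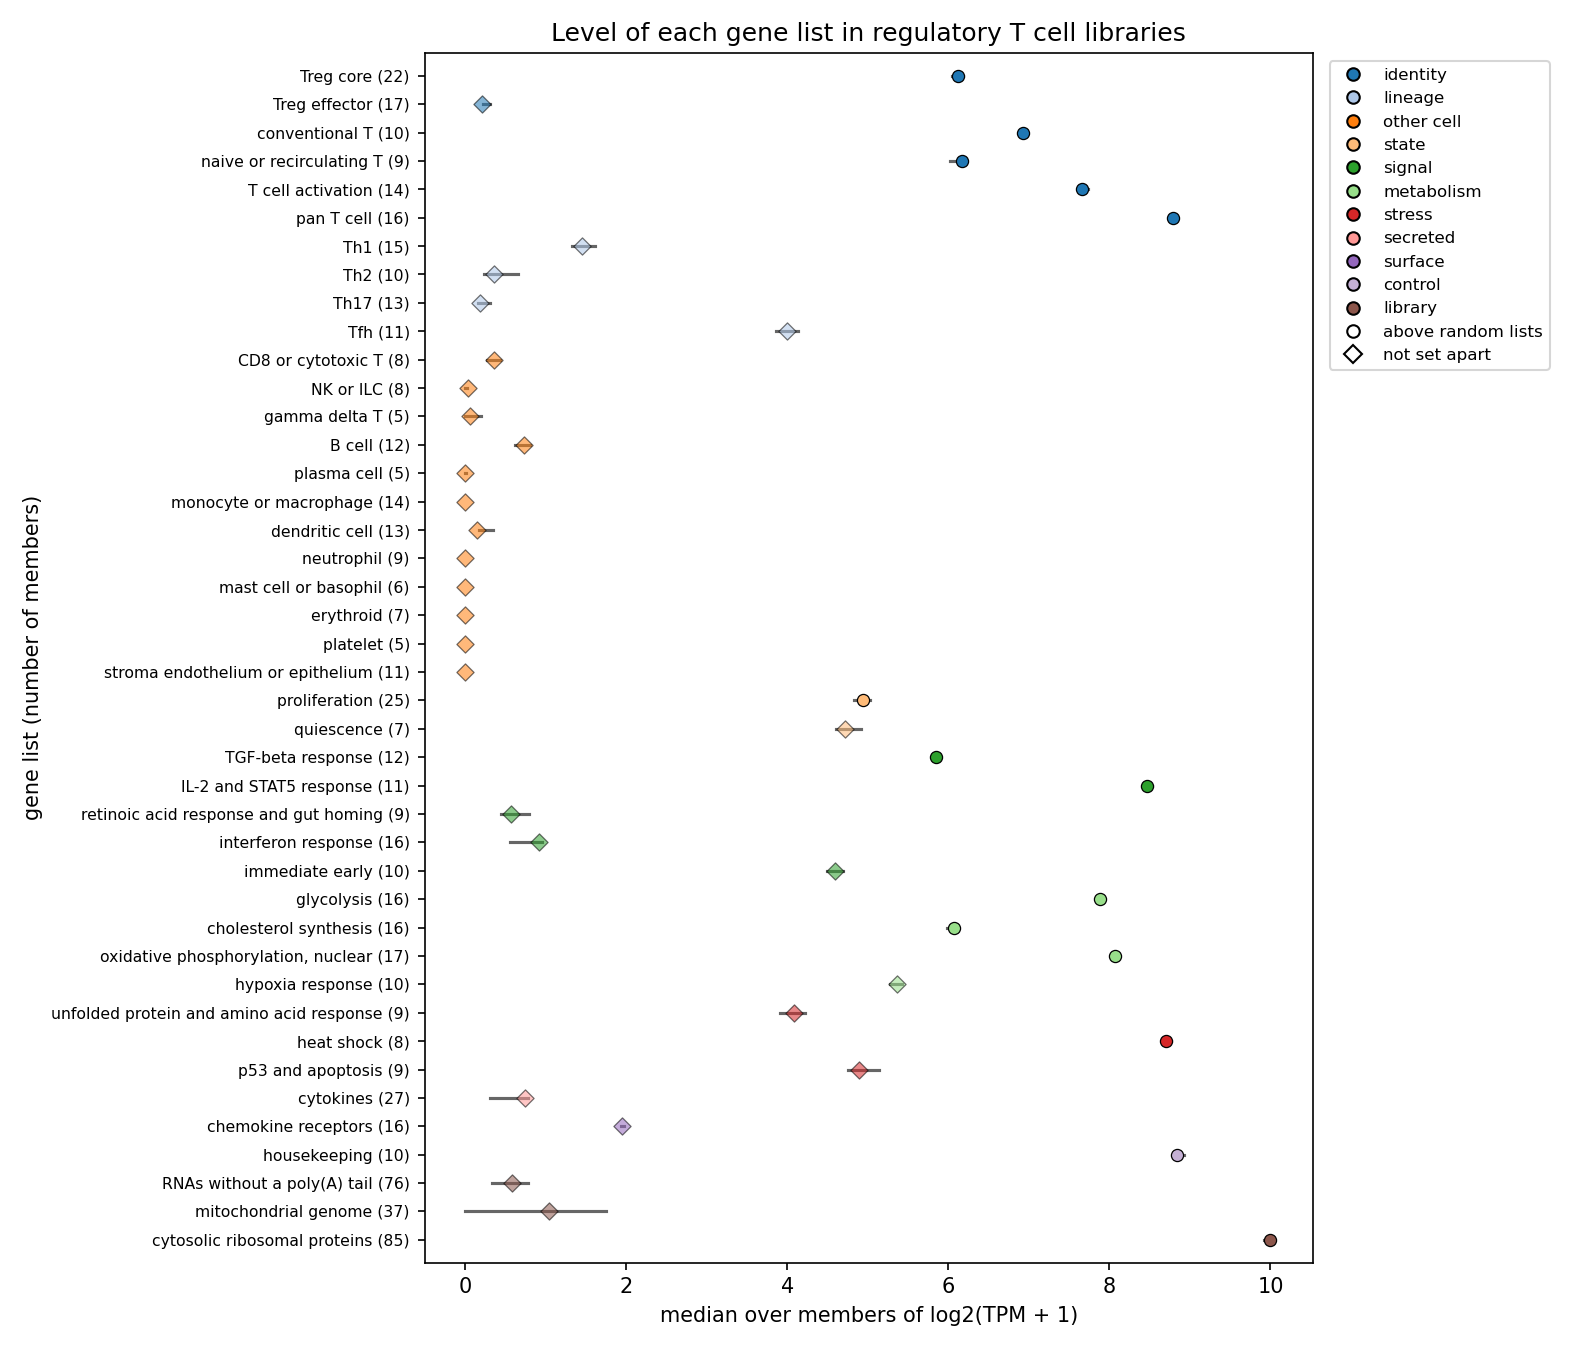
Median over members of log2(TPM + 1) for the 42 gene lists, with members in brackets; the marker is the median of means over 3 libraries, and the bar spans the 3 library values. Circles mark the 14 lists above random lists of protein-coding genes, diamonds the other 28, and colours the kind of list.

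The proliferation list ranged widely in level. Mcm3 and Mcm5, subunits of the replicative helicase, reached 841 ± 36.02 and 761 ± 44.2 TPM. Ccnb1 and Ccnb2, the cyclins of mitotic entry, were at 5.9 ± 0.91 and 2.49 ± 0.424 TPM. All 25 proliferation genes reached 1 TPM in every library, with a median of 29.8 TPM (adjusted p = 0.0194); against genes at 1 TPM or more the list lay at percentile 49.0. Among 7 quiescence genes, Btg1 (130 ± 7.29 TPM) and Klf2 (71.5 ± 8.02) were highest and Cdkn2c (3.97 ± 0.55) and Cdkn1b (15.1 ± 1.22) lowest, and the median of 25.5 TPM was not set apart (adjusted p = 0.376).

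Targets of interleukin-2 and of TGF-beta signalling stood above random lists. The interleukin-2 and STAT5 list had a median of 354 TPM (adjusted p = 0.00084), led by Lta (lymphotoxin alpha, 1575 ± 106 TPM) and Il2rb, with Socs2 (10.8 ± 1.56) and Socs3 (15.3 ± 1.07) lowest. The TGF-beta list had a median of 57.5 TPM (adjusted p = 0.0077), led by Tgfb1 itself (177 ± 7.97) and the SMAD corepressor Ski (141 ± 4.32). Against genes at 1 TPM or more that list lay at percentile 91.0, no longer set apart.

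Interferon, retinoic acid and immediate early lists were not set apart. Of 16 interferon response genes, Bst2 (263 ± 17.2 TPM) and Igtp (50.9 ± 11.9) were highest, Mx1 had no fragment and Rsad2 had 1 (median 0.938 TPM, adjusted p = 0.919). In the retinoic acid and gut homing list, Rara (119 ± 14.4 TPM) and Itgb7 (96.6 ± 3.26) contrasted with Ccr9 (1 fragment) and Cyp26b1 (none), with a median of 0.493 TPM (adjusted p = 0.98). Ier2 and Jund were at 522 ± 39.2 and 510 ± 42.5 TPM while Fos and Fosb were at 0.856 ± 0.456 and 0.372 ± 0.12, giving an immediate early median of 23.6 TPM (adjusted p = 0.211).

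Metabolic genes were high. Ldha and Pkm, the last enzymes of glycolysis to lactate, were at 2612 ± 83.9 and 1450 ± 109 TPM (1326, 1533 and 1490 TPM in replicates 2, 3 and 4), whereas the transporters Slc16a3 and Slc2a3 were at 7.27 ± 1.57 and 16.7 ± 0.122. The glycolysis median was 246 TPM and that of nuclear oxidative phosphorylation genes 268 TPM, led by the ATP synthase genes Atp5b (1564 ± 37.4) and Atp5a1 (1504 ± 36.5), with Ndufs1 (55.5 ± 1.96) and Cycs (64.3 ± 1.07) lowest; adjusted p was 0.00084 for both. Cholesterol synthesis genes had a median of 66.6 TPM (adjusted p = 0.0015), from Srebf2 (368 ± 27.0) and Hmgcs1 (234 ± 19.2) to Lss (26.3 ± 0.807) and Fdps (19.1 ± 1.51). Against genes at 1 TPM or more, cholesterol synthesis lay at percentile 97.0, no longer set apart. The hypoxia list, with Mif at 2016 ± 139 TPM, Slc2a1 at 99.98 ± 5.98, Vegfa at 8.7 ± 1.05 and Ndrg1 at 4.82 ± 0.256, had a median of 40.3 TPM and an adjusted p of 0.0594.

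Chaperones were abundant, with 6 of 8 heat shock genes at 10 TPM or more in every library and 2 below 1 TPM. Hspa8 and Hspd1 were at 2713 ± 54.4 and 1785 ± 72.8 TPM, and Hspa1a and Hspa1b, which form a near-identical pair and are uncertain, at 0.0847 ± 0.127 and 0.475 ± 0.234; the heat shock median was 462 TPM (adjusted p = 0.00084). In the unfolded protein and amino acid list, Hspa5 (816 ± 5.76 TPM) and Atf4 (723 ± 19.3) contrasted with Ddit3 (8.92 ± 2.24) and Chac1 (4.32 ± 0.849), and the median of 15.97 TPM was not set apart (adjusted p = 0.453). Of the p53 and apoptosis genes, Bax (355 ± 34.3 TPM) and Ccng1 (181 ± 12.5) were highest and Pmaip1 (5.097 ± 0.711) and Fas (12.5 ± 0.0415) lowest (median 29.0 TPM, adjusted p = 0.211).

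Secreted factors and chemokine receptors were expressed as a few genes each. Of 27 cytokine genes, 7 reached 100 TPM in every library and 13 stayed below 1 TPM; Lta and Tnf led, and Il22 and Il6 had no fragment. Of 16 chemokine receptors, Ccr7 and Ccr8 exceeded 800 TPM, 8 stayed below 1 TPM, and Ccr1 and Ccr10 had no fragment. The medians of 0.71 and 4.71 TPM were not set apart (adjusted p = 0.905 and 0.821).

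Among the 10 most abundant protein-coding genes outside the mitochondrial genome were ribosomal protein and elongation factor genes, with a chaperone and an actin gene. The elongation factor Eef1a1 was at 13780 ± 684 TPM, followed by the chaperone Hsp90ab1 (9416 ± 141), the ribosomal protein genes Rplp1 (9337 ± 542) and Rpl8 (8290.5 ± 606), Actb (6659 ± 149), the elongation factor Eef2 (6650 ± 472), Rplp0 (6018 ± 459), Rps15 (5414 ± 235), Rps2 (5394 ± 229) and Rpl4 (5301 ± 142). The 85 cytosolic ribosomal protein genes had a median of 1016 TPM and the 10 housekeeping genes 471 TPM (adjusted p = 0.00084 for both); Rpl10l and Rpl3l had no fragment. The lowest housekeeping genes were Tbp (11.3 ± 0.743 TPM) and Rpl13a (182 ± 3.19).

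RNAs without a poly(A) tail were scarce apart from 1 gene. Rpph1, the RNA of ribonuclease P, was at 222 ± 51.2 TPM and Hist1h3a at 15.8 ± 4.06, while 39 of 76 such genes stayed below 1 TPM in every library, Hist1h1t and Hist1h2aa among those with no fragment (median 0.559 TPM, adjusted p = 0.905). Histone genes share sequence with their copies, so their counts are uncertain. Mitochondrial genes took 0.697%, 0.567% and 0.695% of fragments (95% Wilson intervals 0.694% to 0.699%, 0.565% to 0.569% and 0.693% to 0.696%), led by mt-Co1 (5803 ± 753 TPM) and mt-Nd1 (3866 ± 377). The median over all 37 mitochondrial genes, most of them transfer RNAs, was 1.66 TPM (adjusted p = 0.905), and mt-Atp8 and mt-Nd4l, which overlap a neighbour, had no counted fragment.

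The largest differences between the 3 libraries were in sex-linked genes. Xist, the RNA that silences the inactive X chromosome in females (chromosome X, 103460375 to 103483217), had 27625, 85 and 18895 fragments in replicates 2, 3 and 4, or 126, 0.331 and 36.1 TPM, a highest-to-lowest CPM ratio of 374. The Y-linked genes were the reverse. Ddx3y had 8, 2932 and 4314 fragments (0.126, 39.3 and 28.4 TPM), Eif2s3y 5, 2470 and 4147 (0.0985, 41.4 and 34.1 TPM), Kdm5d 4, 2084 and 2959 (0.0216, 9.59 and 6.68 TPM) and Uty 1, 661 and 960 (0.00837, 4.71 and 3.35 TPM). All 5 were called. Genes of chromosome Y took 0.00153% of fragments in replicate 2 (95% Wilson interval 0.00141% to 0.00165%), 0.0192% in replicate 3 (0.0188% to 0.0196%) and 0.0152% in replicate 4 (0.0149% to 0.0154%). Without replicate 2, the ratios of the 4 Y-linked genes were 1.24 to 1.47 and none was called.

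**Figure D3:**
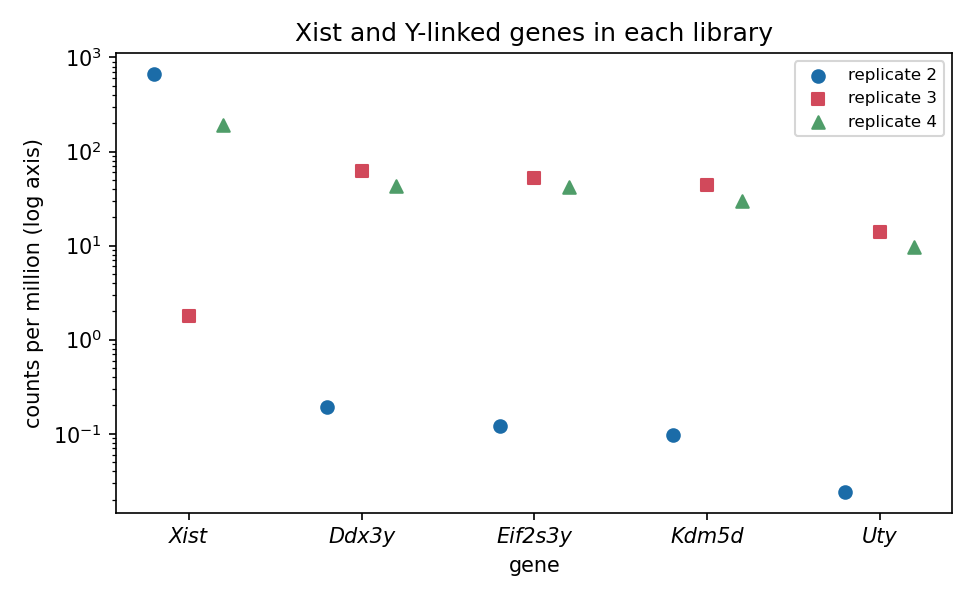
CPM on TMM effective library sizes (log axis) of Xist and 4 Y-linked genes in replicates 2, 3 and 4, 1 point per library with no error. Xist is at 1.79 in replicate 3 and 191 in replicate 4; the 4 Y-linked genes are below 0.2 in replicate 2.

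Beyond these, differences of 2-fold or more at good depth were few. H2-Q6, a class I MHC gene that shares reads with near-identical neighbours and is uncertain, had 31.7, 8.06 and 21.2 CPM in replicates 2, 3 and 4. The X-linked ubiquitin ligase gene Mid1 had 11.4, 4.1 and 6.9 CPM, and the cohesin gene Stag3 had 1.91, 3.05 and 6.22. Arhgap18, Il4i1, Pygm, Sez6l2, Efr3b, Mss51 and 1700109H08Rik were lowest in replicate 3, with ratios of 2.5 to 3.63, as was Mgst3 (2.62). Smoc1 (7.24), Rbm44 (4.29), Cyp4f16 (2.93) and the histone gene Hist1h2bj (2.59, uncertain) were lowest in replicate 2. Apart from H2-Q6 and Mid1 these genes had under 7 CPM. Without replicate 3, the 10 of them lowest there were not called (ratios 1.05 to 1.66), without replicate 2 Smoc1, Cyp4f16, Mid1, Mgst3 and Hist1h2bj were not (1.14 to 1.75), and without replicate 4 Stag3 was not (1.60).

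In all, 1496 of 13688 genes (10.9%) were called by the chi-square test, 759 of them protein-coding, 52 on chromosome X and 6 on chromosome Y; 93 had a mean count of 100 or more. At any ratio, 9685 genes (70.8%) had an adjusted p under 0.05, so that differences beyond counting error were common and mostly small. Called genes were lowest in replicates 2, 3 and 4 in 496, 709 and 291 cases. The count was 774 without replicate 2, 514 without replicate 3 and 530 without replicate 4, and 767 with counts divided by 2.

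Of the 22 core genes of Treg identity, 2 were called between libraries, Itgae and Entpd1, the scarcest, against 10.9% of all tested genes; the count adjusted over the list alone was also 2. Genes that were not called could still differ beyond counting error at a ratio under 2, as with Ctla4 (highest to lowest CPM 1.21). No member of the conventional T, naive, activation, pan T cell, proliferation, glycolysis, cholesterol synthesis or oxidative phosphorylation lists was called. Calls were rare among well-counted genes at large, with 96 of 10374 genes called at a summed count of 300 or more. The absence of calls in lists of abundant genes therefore tells little about those lists. Across all lists, 41 of 435 tested genes were called, 17 of them in the list of RNAs without a poly(A) tail, all histone genes but Terc. Counts adjusted over the list alone were the same in every list but that of B cell genes (3 over all genes, 2 over the list alone).

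Small shifts of whole lists were found between libraries. The interferon response list was highest in replicate 2 (median log2 difference from the other libraries 0.30 over 11 genes, percentile 99.95 of matched lists). It was lowest in replicate 3 (-0.30, percentile 0.41). With an offset of 5 CPM these values were 0.13 and -0.08, still outside. Of the 11, 4 were called, both over all genes and adjusted over the list alone. The most abundant member, Bst2, went the other way (65.1, 75.4 and 71.4 CPM in replicates 2, 3 and 4). Igtp, the next, followed the median (37.1, 23.4 and 31.1 CPM). Mitochondrial genes were lowest in replicate 3 (-0.23 over 14 genes, percentile 0.01; -0.10, percentile 0.81, after centring on genes of like GC content). Glycolysis genes were lower in replicate 2 (-0.14 over 16 genes, percentile 0.11) and higher in replicate 3 (0.13, percentile 100), as were immediate early genes (-0.20 and 0.15 over 10 genes). After centring on genes of like GC content both immediate early values were inside (-0.03 and 0.07), as were those of mitochondrial genes in replicate 2 (-0.05) and housekeeping genes in replicate 4 (-0.06), while glycolysis in replicate 2 (-0.07) and mitochondrial genes in replicate 4 (0.17) stayed outside. After centring on exon length pan T cell genes in replicate 4 (-0.04) were inside. The list medians of hypoxia (0.16), quiescence (0.18) and ribosomal protein genes (0.11 over 82 genes) were highest in replicate 3. Single members of the hypoxia and quiescence lists did not all follow. Klf2, Mif and Slc2a1 were highest in replicate 3, but Btg1, Cdkn1b, Cdkn2c and Ndrg1 in replicate 2 and Vegfa in replicate 4. The remaining pairs outside were quiescence (-0.20), pan T cell (-0.06), ribosomal protein (-0.05), housekeeping (-0.07) and mitochondrial (0.11) genes in replicate 4 and mitochondrial genes in replicate 2 (0.16). In sum, 16 of 96 pairs of list and library, from 9 of 32 lists, lay outside the central range of matched lists. Lists of genes drawn singly would give 4.8 by chance, but members of a list may vary together. The values of a list also depend on each other, since each library is set against the other 2. Without replicate 3, 8 of 64 pairs lay outside, which are 4 lists counted once for each of the remaining libraries, whose values mirror each other. Without replicate 3, the values of glycolysis (-0.10) and mitochondrial genes (0.05) in replicate 2 and of quiescence (-0.14), mitochondrial (-0.05), pan T cell (0.00010) and ribosomal protein genes (0.00018) in replicate 4 were inside, and interferon genes in replicate 2 (0.19) stayed outside. Without replicate 2, those of immediate early (0.08) and glycolysis genes (0.06) in replicate 3 and housekeeping genes (-0.04) in replicate 4 were inside, as were quiescence (0.15) and hypoxia genes (0.10) in replicate 3 without replicate 4. Values that moved by over 1.5 times and stayed outside were those of hypoxia genes in replicate 3 (0.10) and mitochondrial (0.20) and ribosomal protein genes (-0.11) in replicate 4 without replicate 2, of quiescence (-0.13) and mitochondrial genes (0.07) in replicate 4 and immediate early (-0.13) and mitochondrial genes (0.10) in replicate 2 with the offset of 5 CPM, and of ribosomal protein genes in replicate 4 (-0.03) with log2(TPM + 1). Each value is 1 library against 2, with no replicate check.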

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

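Of the alternatives, centring on GC content or exon length and leaving out chromosomes X and Y were chosen after the data were seen. The posterior mean TPM planned as an alternative was not run, because no such values are used here, and FPKM was computed from the counts. Foxp3 stayed above Tbx21, Gata3 and Bcl6 in all 7 alternatives. The log2 difference from Tbx21 became 7.22 and that from Bcl6 3.73 with a pseudocount of 0.1; with FPKM they became 4.47 and 3.17, and that from Gata3 1.74, since the pseudocount then weighs more on lower values. In CPM, where gene length counts, the differences from Tbx21 and Bcl6 were 6.19 and 2.90.

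The 14 lists above random lists stayed above in 6 of 7 alternatives. Random lists from genes at 1 TPM or more in a library, a higher background by construction, left 10 of the 14 above and put 22 lists below instead of 0. Percentiles there fell across the middle for proliferation (49.0), Th1 (0.01) and retinoic acid, interferon, cytokine, chemokine receptor, poly(A)-lacking and mitochondrial lists (0 each), and, with no call either way, for Tfh (12.5), quiescence (40.2), immediate early (33.1), unfolded protein (16.3) and p53 (47.5) lists. With only members at 1 TPM or more, the core list exceeded the Th1, Th2 and Th17 lists by 2.45, 1.00 and 1.18 (adjusted p = 0.363, 0.531 and 0.531; over all settings 0.0018 to 0.363, 0.0012 to 0.531 and 5e-05 to 0.531), fewer genes being compared.

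Genes called between libraries numbered 2322 with no count filter, 96 with a summed count of 300 or more, 767 with counts divided by 2, and 514 to 774 without 1 replicate, with fewer libraries to span; other settings gave 1438 to 2198. Of the 96, 93 were among the 1496. Named genes kept their call in 165 of 185 settings; 20 losses all came without 1 replicate. Pairs of list and library outside numbered 8 to 14 without 1 replicate, from 64 instead of 96 pairs (4 to 7 lists, since values of the remaining libraries mirror each other), and 16 to 20 otherwise; an offset of 5 CPM took the interferon values in replicates 2 and 3 from 0.30 and -0.30 to 0.13 and -0.08. Depth limits genes of low count: 1403 of the 1496 calls had a mean count under 100.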

Other observations

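The genes of this part were chosen after their values were seen, as were the split of the proliferation list and the test that cells of both sexes made up replicate 4; the other tests were written before their results were seen, but the preset readings of the shared-read and interferon tests on class I genes were set aside after their values were seen, for the reasons given there. Within the proliferation list, the 13 members that act in DNA replication or its onset were set beside the 12 that act in mitosis or late cycle. The 6 Mcm genes lay between 361 and 869 TPM in every library and Pcna, the polymerase clamp, was at 561 ± 15.2 TPM (SD, n = 3). Mki67, the common proliferation marker, was at 13.3 ± 0.881 TPM. Medians were 377 against 14.1 TPM, a log2 difference of 4.65 (4.55, 4.70 and 4.66 in replicates 2, 3 and 4), with no test, since the split was made from these levels.

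Several ligands of the TNF family were abundant. Beside Lta and Tnf, Ltb was at 502 ± 35.2 TPM, the CD40 ligand gene Cd40lg at 220 ± 6.54 and Tnfsf11 (RANKL) at 175 ± 7.53. The chemokine gene Xcl1 was at 223 ± 8.55 TPM, whereas Csf2 was at 0.427 ± 0.27. The chemokine receptor gene Ccr2 was at most 0.0121 TPM in any library, while Cxcr3, Cxcr4 and Cxcr5 lay between 11.4 and 15.3. Inhibitory and effector genes were uneven, with Lag3 at 204 ± 11.99 TPM and the effector Treg factor Prdm1 (Blimp-1) at 0.0423, Gzmb at 0.122, Havcr2 (TIM-3) at most 0.0377 in any library and Il1rl1 (ST2) at 0.144. The Ikaros family ran from Ikzf1 (328 ± 11.99 TPM) through Ikzf4 and Ikzf3 (29.2 ± 3.66) to Ikzf2. Cd8b1 was at 26.9 TPM with Cd8a at 0.416 and Cd4 at 591.

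Replicate 4 held both Xist and Y-linked transcripts, replicate 2 mainly the former and replicate 3 the latter. On a scale from replicate 3 (0) to replicate 2 (1) its Xist level was 0.283, and on the opposite scale its mean Y-linked level was 0.721; the 2 shares add up to 1.004, so cells of both sexes in replicate 4 are a candidate explanation. Genes that escape X inactivation went the same way: Kdm5c, Eif2s3x and Ddx3x were higher in replicate 2 than in replicate 3 by 0.53, 0.75 and 0.27 (log2), and their median position in replicate 4 was 0.259, though Kdm5c lay at 0.57. A mixture of the finished libraries of replicates 2 and 3 is argued against, since 17.0% of 7410 well-counted genes (1263) lay outside the range of those libraries by over 3 standard errors. In replicates 2 and 3, Xist had 27625 and 85 fragments and Ddx3y 8 and 2932, with Eif2s3y, Kdm5d and Uty also higher in replicate 3. These values argue against 1 animal as the source of both libraries. Whether cells were pooled within a library, as replicate 4 may have been, stays open, because the labels give 1 donor identifier and no sex.

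Some class I MHC genes differed: H2-Q5 and H2-Q6 were higher in replicate 2 than in replicate 3 by 1.37 and 1.98 (log2), H2-Q7 had 73.6 against 31.9 CPM, and their regulator Nlrc5, which has no such copy and was not called, was higher by 0.88, whereas the abundant class I genes H2-K1, H2-D1 and B2m differed by 0.10, 0.03 and 0.30. Reads shared between near-identical H2-Q genes could add to this: 8 single-copy antigen processing genes had a median of -0.0152, which by the preset bound would have counted for shared reads, but that reading was set aside after the value was seen because 4 of 8 genes went each way (median absolute deviation 0.142). For a stronger interferon response in replicate 2, 10 other interferon-regulated genes had a median of 0.24, 8 of 10 higher. That lay at percentile 96.6 of matched lists, which by the preset bound would have ruled this response out. Such a reading too was set aside after the value was seen. The percentile lies just inside the bound, and the interferon list fixed beforehand lay at percentile 99.95 in replicate 2. Of the 2 most abundant genes of that list, Igtp followed the shift and Bst2 went the other way (65.1 against 75.4 CPM in replicates 2 and 3). A stronger interferon response in replicate 2 therefore stays open. The share of female cells alone cannot be told apart from these, because the median position in replicate 4 was 0.557 against 0.283 for Xist, yet H2-Q5 lay at 0.253. The design names no second group, so no difference between groups was tested as an explanation.

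The shifts of whole lists between libraries were set against composition trends: across genes, the log2 ratio of replicate 2 to replicates 3 and 4 fell with GC content (Spearman's rho -0.43 and -0.47; 0.03 for replicate 3 over 4; genes are not independent replicates). After centring on genes of like GC content 20 of 96 pairs lay outside, against 16 before, 12 of them shared. By the preset bound this counted against a GC-content trend for the shifts as a whole, but the count cannot decide it. Percentiles can move outward while a shift shrinks: ribosomal protein genes in replicate 2 went from -0.05 (percentile 6.4) to -0.03 (percentile 0.56). The interferon shift in replicate 2 went from 0.30 to 0.22 (percentile 99.65), but 3 pairs that shrank and fell inside may follow GC content: immediate early genes in replicates 2 (-0.20 to -0.03, percentile 23.7) and 3 (0.15 to 0.07, percentile 93.2) and mitochondrial genes in replicate 2 (0.16 to -0.05, percentile 9.99). Glycolysis in replicate 2 (-0.14 to -0.07) and mitochondrial genes in replicate 3 (-0.23 to -0.10) shrank and stayed outside, whereas housekeeping genes in replicate 4 hardly moved but fell inside (-0.07 to -0.06, percentile 2.83). Centring on exon length left 18 pairs outside, 15 of them shared; pan T cell genes in replicate 4 fell inside (-0.06 to -0.04, percentile 8.46).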
